A study of Homo sapiens with 6 samples.

How the data were processed

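RNA was measured by sequencing in 6 libraries from tumors of MCF7 cells. Per the labels, wild-type (WT) or FLCN knockout (KO) cells were injected into the mammary fat pads of female NSG mice, a strain without functional lymphocytes, the mice received estradiol, and tumors were resected when they had reached a set range of volume. Libraries were made from total RNA with an mRNA kit, per the labels' protocols. The deposited values were whole-number counts per gene for 58051 gene identifiers, in 1 table whose columns carry the sample titles. Per the submitters' processing notes, the tools were bcl2fastq, Trimmomatic, STAR and HTSeq and the genome build was GRCh38. The versions, the annotation release, the treatment of reads that align to several places and the strand setting of the counting are not given in the sources used here. The reference was human, so reads of mouse host cells could enter the deposited counts only where they aligned to human genes.

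Groups were taken from the genotype label. Replicates were numbered 1 to 3 in each group in the order of the deposited samples, and these numbers pair nothing. The sample number in the title of FLCN KO replicate 3 does not follow on from those of the other samples. No label gave a batch, a date, the mouse of origin or the method of the knockout. Library totals ranged from 42949326 to 75329609 counts.

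Genes were filtered with filterByExpr at its default settings, which kept 18182 of the 35993 genes with at least 1 count. Libraries were scaled by TMM, and FLCN KO was compared with WT by the quasi-likelihood F test of edgeR (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment over the tested genes. A gene was called at an adjusted p under 0.05, and every adjusted p of a gene comes from this edgeR test unless another tool is named. The standard error (SE) of a log2 fold change is its size divided by the square root of F. CPM values (counts scaled to a common library size) use the TMM-scaled library sizes and are given as mean ± SD of 3 libraries. For genes with few counts in a group, the ratio of summed counts is given with an exact 95% binomial interval, which covers counting error only, as reads carried no molecular identifiers.

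In all, 18 gene lists and 6 lists of cell type markers were tested with camera (limma) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 24 lists. The same lists were tested with camera with a correlation estimated from the data, and with fry, which asks whether the genes of a list move in 1 direction on balance without comparing them to other genes. The named genes followed a rule: FLCN, FNIP1, FNIP2, TFE3, TFEB and MITF. Added to these were the 8 largest rises and 8 largest falls among called protein-coding genes with an average log2 CPM of at least 2 and no overlap between the groups. From each list, the rule took up to 4 called members with the smallest adjusted p, or the 2 most abundant members where none was called. Lists, named-gene rule, tests and alternatives were fixed before the data were examined, except where stated. Any further gene named was chosen after its values were seen.

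Alternatives were RLE scaling, library totals alone, upper-quartile scaling, no filter on low counts, a stricter filter (at least 1 CPM in 3 libraries and an average log2 CPM of 2), robust dispersion estimates, DESeq2, limma-voom, and leaving out each library. Added after the data were seen were a comparison of WT replicates 2 and 3 with FLCN KO replicates 1 and 2, and a comparison in which each of these close pairs was summed to 1 library. Gene types, positions, transcript lengths and exon overlaps came from GENCODE 29 (GRCh38), which held 57447 of the 58051 identifiers. Whether the authors counted over that release is not given in the sources used here. Among the named genes, exons of FLCN, FNIP1, ENTPD1, HPN, GLIPR1, SERHL2, CRABP1, IGFBP5, SQSTM1, WIPI1, UVRAG, OPTN, CTSA, ASAH1, ATP6V1C1, ATP6V1D, GAPDH, ALDOA, BHLHE40, COX4I1, POLG, TPD52L1, MUC1, ITGA6, MCM7, SLC7A5, OAS1, PSMB8, ICAM1, LIF, TNFAIP3, SPARC and PLIN4 overlap exons of another gene. Their values, and those of SERHL2, GAPDH and the mitochondrially encoded genes, which have near-identical copies or pseudogenes, are uncertain to that extent. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15 were used.

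The gene test was tested on simulated data for this comparison, with counts drawn for the 18182 tested genes and a known set of genes changed. After the filter was run again on the simulated counts, 17851 genes were tested. It recovered 1 of 55 genes changed 1.5-fold, 32 of 67 changed 2-fold and 69 of 78 changed 4-fold, and 3 of its 105 calls were genes that had not been changed. Going by these counts, genes that differ by 1.5-fold or 2-fold can often miss the threshold here, and some that differ by 4-fold can. The list test recovered 3 of 3 shifted lists and called 0 of 20 others. All members of a shifted list were raised by the same amount. That amount was above the median log2 fold change of every gene list below except MiT/TFE targets (1.20). The recovery therefore does not show whether smaller list shifts, such as 0.34 for autophagy genes, would be found. Counts were drawn independently for each gene and library, so neither correlated genes nor close pairs of libraries were simulated. The simulation therefore does not check the list test where genes vary together, as for hypoxia-inducible factor targets (estimated correlation 0.86).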

Results

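Gene counts were obtained from 6 libraries of tumors that MCF7 cells formed in mice. MCF7 is an estrogen receptor-positive human breast cancer line. The series asks how loss of FLCN changes breast tumor growth through a program that depends on TFE3. FLCN encodes folliculin, which acts with FNIP1 and FNIP2 at the lysosome and restrains the transcription factors TFE3 and TFEB. The labels gave 3 libraries as WT and 3 as FLCN KO. Total counts were 51490911, 42949326 and 60691389 in WT replicates 1 to 3, and 61660422, 48944209 and 75329609 in FLCN KO replicates 1 to 3. The labels do not say that every library came from a separate mouse, so p-values measure the spread between these libraries, which may in part be technical.

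The libraries of a group were not equally far apart. WT replicates 2 and 3 differed by a chi-square of 4.68 per degree of freedom and FLCN KO replicates 1 and 2 by 4.46, which is more than counting noise but does not show that they came from separate tumors. Each was counted as a library of its own because the labels list it as one, and with these pairs summed 217 genes changed in place of 1582. The other pairs within a group lay between 98.6 and 128, and pairs from different groups between 113 and 307. WT replicate 1 and FLCN KO replicate 3 thus stood apart from their groups. The first principal component of log2 CPM held 54.9% of the variance and separated the groups, with WT between −59.9 and −12.8 and FLCN KO between 33.0 and 62.5. The second held 24.98% and set WT replicate 1, at 62.1, apart from the rest.

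The transcript of the targeted gene was not lower in the libraries labelled FLCN KO. FLCN (ENSG00000154803, GRCh38 chromosome 17, 17212212 to 17237188, minus strand) had 1755, 1012 and 1425 counts in WT replicates 1 to 3 and 2926, 2387 and 3494 counts in FLCN KO replicates 1 to 3. This corresponds to 26.4 ± 4.90 CPM in WT and 48.6 ± 1.26 CPM in FLCN KO (SD, n = 3 each). The log2 fold change was 0.88 ± 0.15 (SE), with an edgeR adjusted p of 0.012, and all 3 KO-labelled libraries lay above all 3 WT libraries. A permutation of the CPM values gave an exact two-sided p of 0.1, the smallest that 3 against 3 libraries can give. The call ended without WT replicate 2 (adjusted p = 0.066), WT replicate 3 (0.063), FLCN KO replicate 1 (0.056) or FLCN KO replicate 2 (0.061), at log2 fold changes between 0.81 and 0.89. Gene-level counts cannot tell an edited from an intact transcript, and 1161 of the 9786 exonic bases of FLCN also belong to AC055811.2 on the same strand. The counts therefore do not check the labels, and each direction below refers to the libraries labelled FLCN KO.

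The partners of folliculin also rose in these libraries. FNIP2 went from 5.90 ± 1.64 to 31.1 ± 9.003 CPM, a log2 fold change of 2.40 ± 0.27 (adjusted p = 0.0023), and FNIP1 from 18.6 ± 8.001 to 50.9 ± 12.9 CPM (1.45 ± 0.31, adjusted p = 0.028). MITF, a transcription factor of the same family as TFE3 and TFEB, rose from 3.89 ± 0.68 to 8.40 ± 1.03 CPM (1.11 ± 0.19, adjusted p = 0.013). TFE3 itself had 77.4 ± 6.63 CPM in WT and 71.9 ± 10.2 CPM in FLCN KO (adjusted p = 0.66), and TFEB had 7.93 ± 1.305 and 6.84 ± 0.59 CPM (adjusted p = 0.47). For TFE3 and TFEB the difference in transcript level did not exceed the spread between libraries in this test. FNIP1 missed the threshold without WT replicate 2 (adjusted p = 0.089), WT replicate 3 (0.11), FLCN KO replicate 1 (0.065), FLCN KO replicate 2 (0.069) or FLCN KO replicate 3 (0.083), and MITF without WT replicate 2 (0.057), WT replicate 3 (0.0505) or FLCN KO replicate 1 (0.058).

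**Figure D1:**
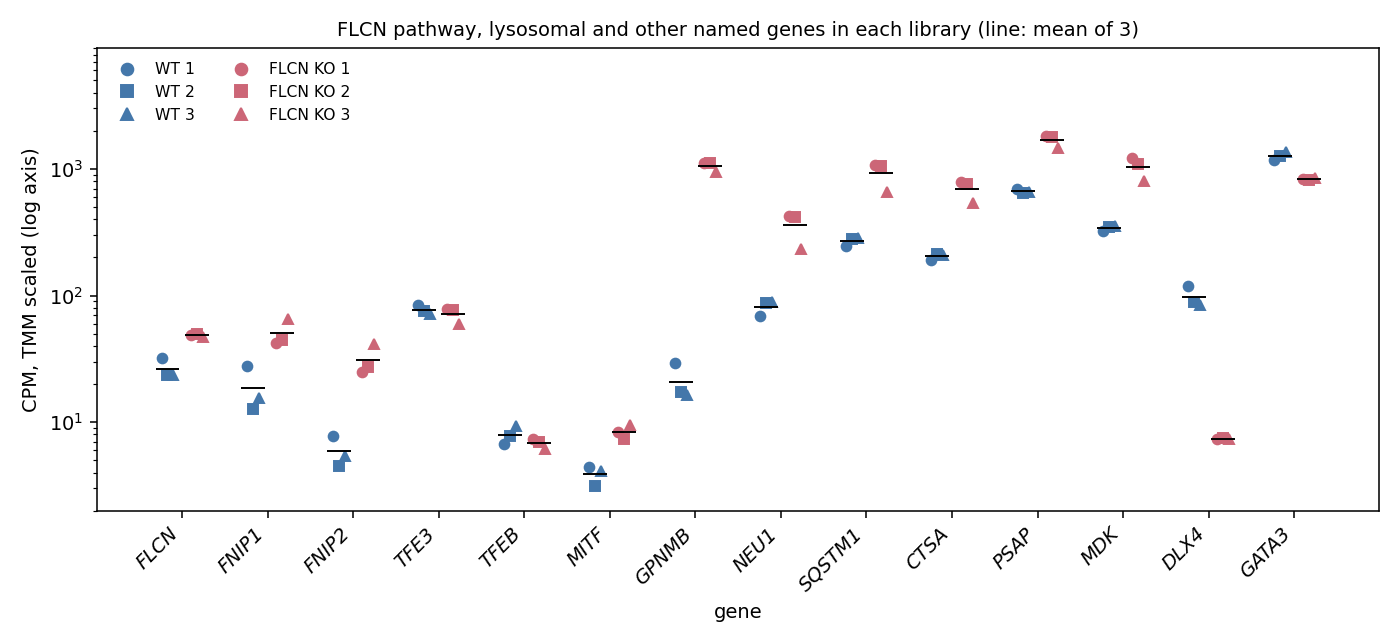
CPM of 14 named genes in each library (log axis), with WT in blue, FLCN KO in red, 1 symbol per replicate and a line at the mean of 3 libraries. FLCN lies higher in the KO-labelled libraries (48.6 against 26.4 CPM), as do GPNMB, NEU1, SQSTM1, CTSA, PSAP and MDK, while TFE3 and TFEB overlap and DLX4 and GATA3 lie lower.

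Of 18182 genes tested, 1582 (8.70%) changed between FLCN KO and WT, 1037 higher and 545 lower in the KO-labelled libraries. At least 2-fold changes made up 882 of these, 566 higher and 316 lower. The largest rises among the named genes included GPNMB (ENSG00000136235, chromosome 7, 23235967 to 23275108, plus strand), a transmembrane glycoprotein gene, from 21.0 ± 7.08 to 1058 ± 102 CPM (log2 fold change 5.66 ± 0.27, adjusted p = 6.9e-05). MYO7B, an unconventional myosin gene, had 2, 0 and 1 counts in WT and 675, 489 and 341 in FLCN KO, a ratio of 437 (95% counting interval 149 to 2120). RENBP, which encodes renin-binding protein, had 6 counts over the WT libraries and 2333 over the FLCN KO libraries (ratio 338, interval 155 to 923). ENTPD1, which encodes an ectonucleotidase, rose 38.5-fold to 44.0 ± 9.17 CPM, the transporter gene ABCC2 rose 36.2-fold to 27.9 ± 0.26 CPM, the serine protease gene HPN rose 34.0-fold, the acetyltransferase gene SAT2 28.2-fold and GLIPR1 26.0-fold, with adjusted p between 1.3e-05 and 0.00042. HPN and ENTPD1 overlap antisense genes, and 1516 of the 6273 exonic bases of GLIPR1 overlap KRR1 on the other strand, so their counts are uncertain while the strand setting is unknown.

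The largest falls were found in HGFAC, a protease gene that activates hepatocyte growth factor, from 16.8 ± 4.73 to 0.55 ± 0.028 CPM (log2 fold change −4.92 ± 0.26, adjusted p = 0.00012), and in the homeobox gene DLX4, from 97.7 ± 18.9 to 7.38 ± 0.080 CPM (−3.73 ± 0.17, adjusted p = 5.9e-05). SERHL2 (−3.95), CRABP1, a retinoic acid binding protein gene (−3.60), SERINC2 (−3.36), the protocadherin gene PCDH19 (−3.21) and ZMAT1 (−3.01) fell as well, with adjusted p between 0.00038 and 0.0099. IGFBP5, an insulin-like growth factor binding protein gene, fell by 3.61 on the log2 scale (adjusted p = 0.023), with 120.8 CPM in WT replicate 1, 45.7 and 42.8 CPM in WT replicates 2 and 3, 2.40 and 2.56 CPM in FLCN KO replicates 1 and 2 and 12.0 CPM in FLCN KO replicate 3. Its log2 fold change was −2.93 without WT replicate 1 and −4.81 without FLCN KO replicate 3, and it was not called without FLCN KO replicate 1 or FLCN KO replicate 2 (adjusted p = 0.080 and 0.084). CRABP1 and SERHL2 share exonic bases with other genes and are uncertain for the reason given above.

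The number of changed genes depended on the libraries used. It was 4180 without WT replicate 1 and 1280 without FLCN KO replicate 3, but 591 and 601 without WT replicates 2 and 3, 585 and 579 without FLCN KO replicates 1 and 2, and 217 with the close pairs summed to 1 library each. Every call given without WT replicate 1 rests on the close pair, WT replicates 2 and 3, as the whole WT group. Upper-quartile scaling, which moved the median log2 fold change of all genes from −0.016 to −0.126, called 775 genes higher and 781 lower. Of 71 called named genes, 44 kept their call whichever library was left out. The other 27 missed the threshold without at least 1 library, with a highest adjusted p between 0.054 and 0.19. They were FLCN, FNIP1, MITF, IGFBP5, PCDH19, ATP6V1D, ATP6V1E1, UVRAG, TMEM45A, VEGFC, TGFA, POLG, OGDH, CA12, TFF1, CCN5, TPD52L1, GATA3, ITGA6, BST2, INSIG1, SC5D, SLC3A2, CSF1R, ITGAM, EMCN and VWF.

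Genes of the lysosome, and targets of the MiT/TFE transcription factors, were higher in the KO-labelled libraries. Of 19 tested MiT/TFE target genes, 17 rose and 0 fell (17 and 0 adjusted over the list alone), with a median log2 fold change of 1.20. This list holds FLCN, FNIP1, FNIP2, MITF and TFEB themselves. Besides GPNMB, the called members included GDF15, a secreted stress-response cytokine gene, from 91.1 ± 5.01 to 283 ± 42.9 CPM (1.63 ± 0.14, adjusted p = 0.00070), the sialidase gene NEU1, from 81.5 ± 10.5 to 358 ± 107 CPM (2.14 ± 0.24, adjusted p = 0.0021), and SQSTM1, an autophagy receptor gene, from 270 ± 21.7 to 932 ± 241 CPM (1.79 ± 0.20, adjusted p = 0.0022). Of 37 tested genes for lysosomal hydrolases and membrane proteins, 24 rose and 0 fell (29 and 0 adjusted over the list alone), with a median of 0.78. PSAP, the precursor of the saposins, went from 669 ± 23.7 to 1690 ± 199 CPM, CTSA (protective protein/cathepsin A) from 205 ± 10.9 to 694 ± 139 CPM, the acid ceramidase gene ASAH1 from 140 ± 14.3 to 377 ± 28.5 CPM and OSTM1, a partner of a lysosomal chloride transporter, from 22.3 ± 2.75 to 62.0 ± 4.25 CPM, with adjusted p between 0.00072 and 0.00095.

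The proton pump that acidifies the lysosome followed the same direction. Of 16 tested vacuolar ATPase subunit genes, 8 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 0.61. ATP6V1C1 rose by 1.09 ± 0.13 on the log2 scale, ATP6V1B2 by 0.99 ± 0.11, ATP6V1E1 by 0.85 ± 0.16 and ATP6V1D by 0.72 ± 0.14, with adjusted p between 0.0023 and 0.021. Of 31 tested autophagy genes, 7 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 0.34. They included OPTN, an autophagy receptor gene, from 20.9 ± 2.499 to 58.7 ± 10.9 CPM (adjusted p = 0.0025), WIPI1 from 28.6 ± 1.07 to 49.8 ± 2.46 CPM (0.0048) and UVRAG from 18.6 ± 1.58 to 31.8 ± 0.16 CPM (0.0080). SQSTM1, WIPI1 and CTSA have exons that overlap other genes. The MiT/TFE list shares 2 genes with the lysosomal list, 2 with the vacuolar ATPase list and 3 with the autophagy list. Without WT replicate 2, WT replicate 3, FLCN KO replicate 1 or FLCN KO replicate 2, 9, 9, 10 and 10 MiT/TFE targets, 16 lysosomal genes in each case, 2 vacuolar ATPase genes in each case and 3, 3, 5 and 3 autophagy genes rose, and 16 autophagy genes rose without WT replicate 1. With the close pairs summed 6 MiT/TFE targets, 9 lysosomal genes, 0 vacuolar ATPase genes and 1 autophagy gene rose, and under upper-quartile scaling 4 vacuolar ATPase genes rose.

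In the limma camera test the adjusted p was 5.3e-12 for MiT/TFE targets, 4.6e-15 for lysosomal genes, 9.4e-07 for vacuolar ATPase subunits and 3.2e-05 for autophagy genes. The calls were lost with an estimated correlation, with adjusted p = 0.26, 0.26, 0.32 and 0.27. They held in fry (adjusted p = 0.0033, 0.0069, 0.013 and 0.013). None of the 24 lists was called with an estimated correlation, where the smallest adjusted p was 0.26. The camera test with the preset correlation also called MiT/TFE targets in 5, lysosomal genes in 7, vacuolar ATPase subunits in 5 and autophagy genes in 3 of the 9 other splits of the libraries 3 against 3, with smallest adjusted p of 0.00027, 8.3e-09, 1.5e-06 and 0.00021. Each of these splits mixes the groups unevenly and so keeps part of any group difference. A list that differs between the groups can therefore be called in them. Such counts, here and for the lists below, thus give no rate of false calls. The summed leukocyte markers, which moved in the same direction as these lists, had 0.89 ± 0.16 CPM in WT and 1.89 ± 0.52 CPM in FLCN KO. CSF1R and ITGAM carried this rise, while the other markers together went from 0.62 to 0.43 CPM.

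**Figure D2:**
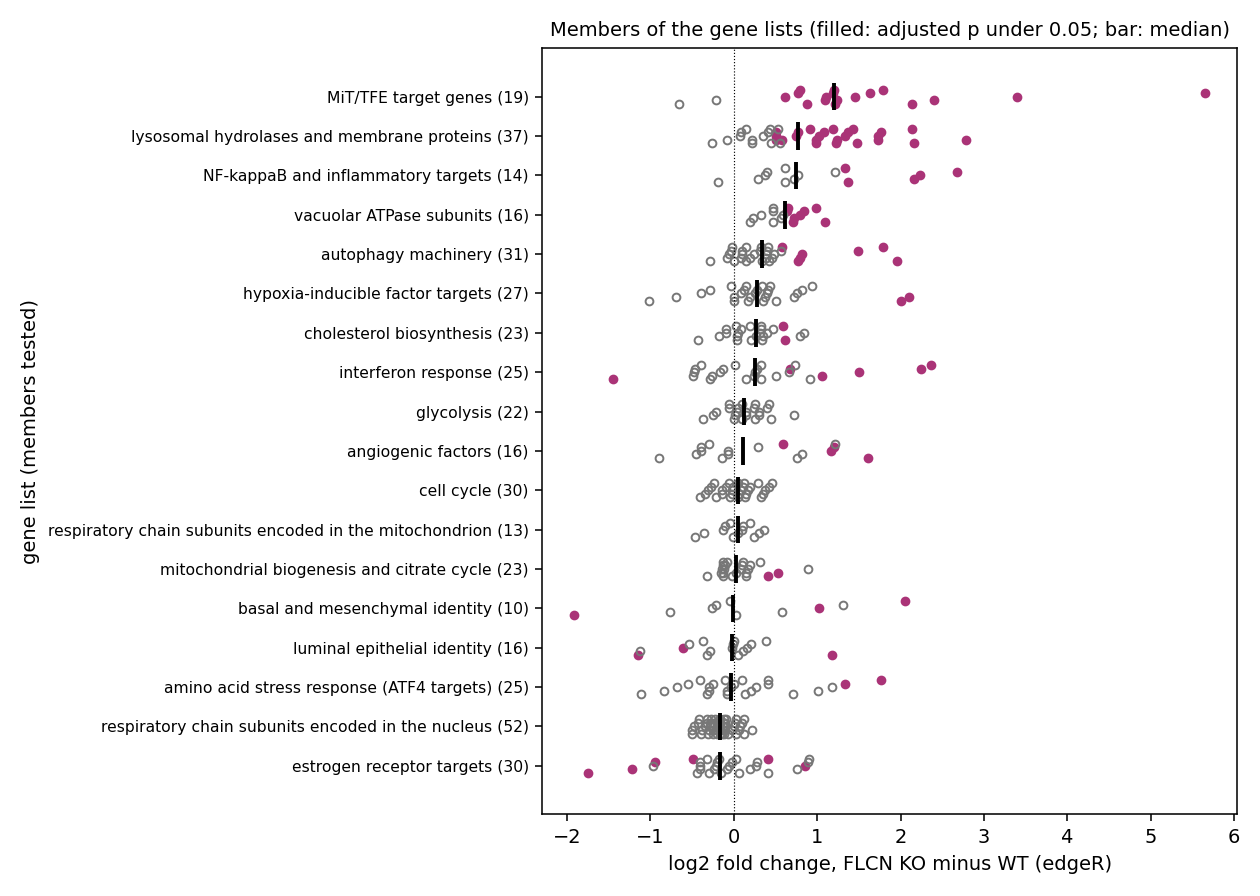
Log2 fold change (FLCN KO minus WT, edgeR) of the tested members of 18 gene lists, with called genes filled, the others open and a bar at each list's median; lists are ordered by median and the number of tested members is in parentheses. The MiT/TFE list has the highest median, 1.20, and estrogen receptor targets the lowest, −0.17.

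Glycolytic genes, targets of hypoxia-inducible factors and angiogenic factors were examined because the series names the Warburg effect and angiogenesis. Of 22 tested glycolysis genes, 0 were called in edgeR (0 adjusted over the list alone, 2 at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma-voom), with a median log2 fold change of 0.12. GAPDH had 5146 ± 930 CPM in WT and 4312 ± 495 CPM in FLCN KO (adjusted p = 0.33), and ALDOA 2971 ± 454 and 3059 ± 492 CPM (adjusted p = 0.89, with the sign changing under upper-quartile scaling and with library totals). The list as a whole had a camera adjusted p of 0.23, and 0.80 with an estimated correlation. Of 27 hypoxia-inducible factor targets, 2 rose and 0 fell (3 and 0 adjusted over the list alone), where 8.70% of all tested genes changed, with a median of 0.28. These were BHLHE40, a transcriptional repressor gene, from 40.2 ± 16.3 to 162 ± 27.3 CPM (2.01 ± 0.28, adjusted p = 0.0048), and TMEM45A, from 1.09 ± 0.37 to 4.71 ± 2.69 CPM (2.11 ± 0.52, adjusted p = 0.046). The list had a camera adjusted p of 0.0071, which was 0.80 with an estimated correlation and 0.37 with fry. It was also called in 3 of the 9 other splits, with a smallest adjusted p of 7.7e-16, below that of the real grouping.

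Of 16 tested angiogenic factor genes, 4 rose and 0 fell (4 and 1 adjusted over the list alone), with a median of 0.11 that was −0.0063 under upper-quartile scaling. Midkine, MDK, rose from 340 ± 17.2 to 1042 ± 211 CPM (1.62 ± 0.16, adjusted p = 0.0013), and VEGFB from 27.0 ± 1.66 to 62.0 ± 15.2 CPM (1.20 ± 0.19, adjusted p = 0.0087). VEGFC, a lymphatic vessel growth factor gene, rose from 0.46 ± 0.027 to 1.03 ± 0.073 CPM (adjusted p = 0.032) and TGFA from 21.0 ± 2.33 to 31.6 ± 3.43 CPM (adjusted p = 0.043). The list had a camera adjusted p of 0.15, and 0.65 with an estimated correlation. It shares 3 genes with the hypoxia-inducible factor list, which shares 3 with the glycolysis list.

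These 3 lists depended on WT replicate 1. In it, 27 of 27 hypoxia-inducible factor targets were above the mean of WT replicates 2 and 3, with a median log2 difference of 1.48. NDRG1, for example, had 629 CPM in WT replicate 1, 36.5 and 34.9 CPM in WT replicates 2 and 3, and 138 to 149 CPM in the KO-labelled libraries. CA9 had 7.94 CPM in WT replicate 1 against 0.46 and 0.68 CPM in WT replicates 2 and 3 and 2.68 to 4.63 CPM in the KO-labelled libraries, and VEGFA had 104 CPM against 31.5 and 32.8 CPM, and 85.4 to 121 CPM. NDRG1, CA9 and VEGFA were chosen after their values were seen. Without WT replicate 1, 23 of the hypoxia-inducible factor targets rose (median 0.98, camera adjusted p = 4.6e-11), 11 of the glycolysis genes rose (0.35, 0.00092), and 8 of 17 tested angiogenic genes rose and 1 fell (0.82, 0.0065). The WT group was then WT replicates 2 and 3 alone, a pair with little spread (chi-square 4.68 per degree of freedom). Calls over all genes also went from 1582 to 4180. The labels do not show that this pair came from separate tumors, so these counts and p-values may overstate the change. Without WT replicate 2 or 3, the hypoxia-inducible factor list was not called (adjusted p = 0.12 and 0.13). Without WT replicate 2, WT replicate 3, FLCN KO replicate 1 or FLCN KO replicate 2, 1 of its members rose, and 2 angiogenic genes rose in each of these cases and without FLCN KO replicate 3. With the close pairs summed, the medians of the hypoxia-inducible factor, glycolysis and angiogenic lists turned negative, at −0.018, −0.078 and −0.022, and the glycolysis median was −0.0014 and −0.0036 without WT replicate 2 and WT replicate 3.

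**Figure D3:**
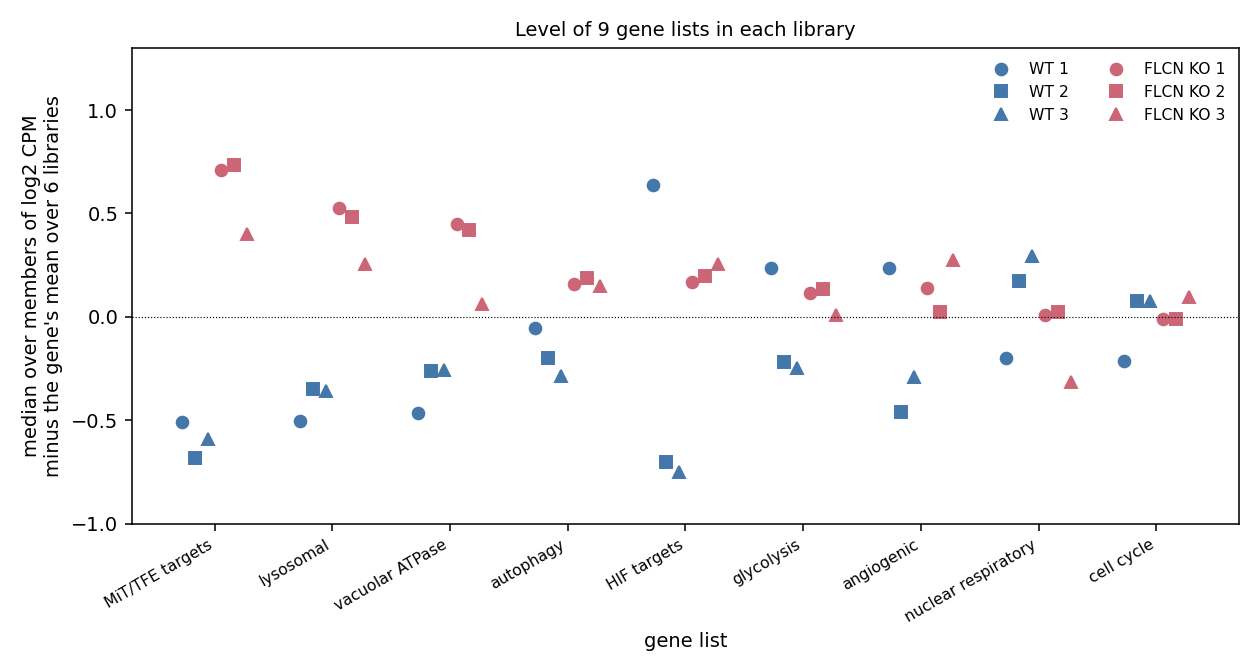
Level of 9 gene lists in each library, as the median over tested members of log2 CPM minus the gene's mean over the 6 libraries; WT is blue, FLCN KO red, 1 symbol per replicate, and HIF stands for hypoxia-inducible factor. For MiT/TFE targets and lysosomal genes all KO-labelled libraries lie above all WT libraries, whereas for HIF targets WT replicate 1 (0.64) lies above the KO-labelled libraries (0.17 to 0.26) and WT replicates 2 and 3 (−0.70 and −0.75) below them.

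Among mitochondrial genes, the 2 respiratory chain lists held 0 called genes, where 8.70% of all tested genes changed. In the simulation 1 of 55 genes changed 1.5-fold was recovered, so 0 calls do not show that these genes were unchanged. Of 52 nuclear genes for respiratory chain subunits, 0 were called in edgeR (0 adjusted over the list alone, 4 at an unadjusted p under 0.05, 0 in DESeq2 and 0 in limma-voom), and 10 fell without WT replicate 1. Their median log2 fold change was −0.17, and 10 of the 52 had a positive value. The most abundant members, ATP5F1B (811 ± 39.5 and 828 ± 50.2 CPM, adjusted p = 0.87) and COX4I1 (491 ± 106 and 511 ± 96.7 CPM, adjusted p = 0.88), changed sign under upper-quartile scaling, and ATP5F1B also with library totals. The camera adjusted p of this list was 0.028, against 0.80 with an estimated correlation, 0.51 with fry and 0.17, 0.44 and 0.45 without WT replicate 2, WT replicate 3 and FLCN KO replicate 3. Other splits called it in 5 of 9 cases, with a smallest adjusted p of 8.4e-10, below that of the real grouping. Of 13 mitochondrially encoded subunit genes, 0 were called in edgeR (0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 0 in DESeq2 and 0 in limma-voom), and 1 rose and 1 fell without WT replicate 1. MT-CO1 had 9962 ± 627 and 11832 ± 1148 CPM (adjusted p = 0.19) and MT-CO2 7237 ± 1057 and 7167 ± 1153 CPM (adjusted p = 0.96). Their median was 0.049, with −0.019 under library totals, −0.061 under upper-quartile scaling and 0.13 without WT replicate 1. The camera adjusted p was 0.83. Of 23 tested genes of mitochondrial biogenesis and the citrate cycle, 2 rose, near the share of all tested genes, and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.59). These were POLG, the mitochondrial DNA polymerase gene (0.52 ± 0.099, adjusted p = 0.018), and the citrate cycle gene OGDH (0.42 ± 0.10, adjusted p = 0.049), and 0 members rose without WT replicate 2, WT replicate 3, FLCN KO replicate 1 or FLCN KO replicate 2, whereas 3 rose and 1 fell without WT replicate 1 and 3 rose and 0 fell without FLCN KO replicate 3.

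Among genes of breast epithelial identity and estrogen response, changes went both ways. Of 30 estrogen receptor targets, 2 rose and 4 fell (3 and 9 adjusted over the list alone, camera adjusted p = 0.23), with a median of −0.17. TFF1, a classical estrogen-induced gene, fell from 265 ± 70.1 to 114 ± 22.9 CPM (adjusted p = 0.019), the carbonic anhydrase gene CA12 from 407 ± 81.6 to 212 ± 11.1 CPM (0.0097), CCN5 from 10.4 ± 4.88 to 3.07 ± 0.67 CPM (0.019) and TPD52L1 from 351 ± 11.4 to 250.3 ± 18.7 CPM (0.028). The growth factor gene AREG (log2 fold change 0.86, adjusted p = 0.032) and PKIB (0.41, 0.047), chosen after their values were seen, rose. Without FLCN KO replicate 3 the camera adjusted p of this list was 0.038. Without WT replicate 1, 6 members rose and 6 fell, without WT replicate 2 or WT replicate 3, 0 rose and 2 fell, without FLCN KO replicate 1, 1 rose and 0 fell, and without FLCN KO replicate 2, 0 rose and 0 fell. Of 16 genes of luminal identity, 1 rose and 2 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.34). The androgen receptor gene AR fell from 96.0 ± 7.51 to 43.2 ± 5.50 CPM (adjusted p = 0.0025) and GATA3, a luminal transcription factor gene, from 1269 ± 83.0 to 831 ± 12.3 CPM (0.0090), while the mucin gene MUC1 rose from 202 ± 17.3 to 457 ± 115 CPM (0.010). In the luminal list 2 rose and 6 fell without WT replicate 1, and without WT replicate 2, WT replicate 3, FLCN KO replicate 1 or FLCN KO replicate 2, 1 rose and 1 fell.

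Of 10 tested genes of basal and mesenchymal identity, 2 rose and 1 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.68). TGFBI, an extracellular matrix gene, rose by 2.06 ± 0.20 (adjusted p = 0.0013) and the integrin gene ITGA6 by 1.02 ± 0.23 (0.033), and S100A4 fell by 1.92 on the log2 scale (0.0057). This list had a median of −0.010, whereas its mean of 0.18 and the direction of its test were positive, and 1 member rose and 1 fell without each library other than WT replicate 1. Its median was 0.44 without WT replicate 1, and 0.11, 0.048 and 0.010 without FLCN KO replicates 1, 2 and 3. Of 30 cell cycle genes, 0 were called in edgeR (0 adjusted over the list alone, 5 at an unadjusted p under 0.05, 1 in DESeq2, 0 in limma-voom, camera adjusted p = 0.66), and 1 rose and 2 fell without WT replicate 1. MCM7, a replication helicase subunit gene, had 614 ± 90.9 and 660 ± 13.7 CPM (adjusted p = 0.63, sign changing under upper-quartile scaling), and TOP2A had 393 ± 24.0 and 332 ± 48.5 CPM (adjusted p = 0.29).

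NF-kappaB and inflammatory targets were higher in the KO-labelled libraries. Of 14 tested members, 5 rose and 0 fell (7 and 0 adjusted over the list alone), with a median log2 fold change of 0.74. ICAM1, an adhesion molecule gene, rose from 7.26 ± 1.53 to 46.4 ± 6.28 CPM (2.67 ± 0.19, adjusted p = 0.00038), the cytokine gene LIF from 2.81 ± 0.27 to 13.2 ± 3.33 CPM (2.23 ± 0.22, 0.0012), the NF-kappaB inhibitor gene TNFAIP3 from 3.89 ± 0.50 to 10.04 ± 0.47 CPM (1.37 ± 0.16, 0.0027) and LCN2, which encodes lipocalin 2, from 6.33 ± 1.38 to 28.3 ± 9.39 CPM (2.16 ± 0.29, 0.0043). TNFAIP2, chosen after its values were seen, was the other called member (1.33, 0.0046). The camera adjusted p was 2.4e-06, which was 0.26 with an estimated correlation and 0.013 with fry. The preset correlation also called this list in 3 of the 9 other splits, with a smallest adjusted p of 7.8e-06. The sum of the leukocyte markers moved in the same direction as this list and the next, with 0.89 ± 0.16 CPM in WT and 1.89 ± 0.52 CPM in FLCN KO. CSF1R and ITGAM carried this rise, while the other markers together went from 0.62 to 0.43 CPM. Of 25 tested interferon response genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 0.25. OAS1, an antiviral sensor gene, rose from 7.49 ± 0.40 to 35.6 ± 6.88 CPM (2.25 ± 0.17, adjusted p = 0.00048), the immunoproteasome gene PSMB8 by 2.37 ± 0.23 (0.0012) and OAS3 by 1.06 ± 0.12 (0.0020), and BST2 fell by 1.45 on the log2 scale (0.015). STAT1 (adjusted p = 0.015) and SAMD9 (adjusted p = 0.036), chosen after their values were seen, also rose. The list missed the threshold in camera (adjusted p = 0.055) and had adjusted p = 0.022 in fry and adjusted p = 0.37 with an estimated correlation. Its camera adjusted p was 0.022 without WT replicate 2 and 0.019 without FLCN KO replicate 3, and 7 members rose and 2 fell without WT replicate 1. Without WT replicate 2, WT replicate 3 or FLCN KO replicate 2, 3 rose and 0 fell, without FLCN KO replicate 1, 4 rose and 0 fell, and without FLCN KO replicate 3, 4 rose and 1 fell. Parts of ICAM1 and PSMB8 overlap antisense or neighbouring genes.

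Of 23 tested cholesterol biosynthesis genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone), with a median of 0.26. They were INSIG1, a regulator of sterol sensing, from 54.8 ± 2.60 to 83.8 ± 6.16 CPM (adjusted p = 0.015), and SC5D, from 28.6 ± 3.14 to 42.9 ± 4.15 CPM (0.037). The camera adjusted p was 0.0090, against 0.61 with an estimated correlation, 0.078 with fry and 0.14 without WT replicate 1. In 6 of the 9 other splits this list was called, with a smallest adjusted p of 0.0037, below that of the real grouping. Of the cholesterol genes 4 rose and 1 fell without WT replicate 1, without FLCN KO replicate 3, 1 rose, and without each of the other 4 libraries 0 rose. Of 25 ATF4 targets of the amino acid stress response, 2 rose and 0 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.68). SLC7A5 rose from 1144 ± 244 to 3895 ± 857 CPM (1.77 ± 0.22, adjusted p = 0.0030) and SLC3A2 from 479 ± 105 to 1205 ± 375 CPM (1.33 ± 0.26, adjusted p = 0.022). Their proteins form 1 amino acid transporter. The list's median was −0.033, whereas its mean of 0.099 and the direction of its test were positive, and the median was 0.18, 0.088 and 0.057 without WT replicate 1, FLCN KO replicate 1 and FLCN KO replicate 2. Of its members 7 rose and 1 fell without WT replicate 1, and without WT replicate 2, WT replicate 3, FLCN KO replicate 1 or FLCN KO replicate 2, 1 rose.

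Markers of other cell types were summed over these human-aligned counts. The 14 leukocyte markers summed to 0.89 ± 0.16 CPM in WT and 1.89 ± 0.52 CPM in FLCN KO. Of these, 2 could be tested and both rose, while the others together went from 0.62 to 0.43 CPM. CSF1R had 5 counts over the WT libraries (4 of them in WT replicate 1) and 81 over the FLCN KO libraries (ratio 14.1, counting interval 5.80 to 44.6, adjusted p = 0.018, log2 fold change 3.71 and, without WT replicate 1, 5.23), and ITGAM rose from 0.24 ± 0.012 to 1.02 ± 0.39 CPM (adjusted p = 0.020). The camera adjusted p of the leukocyte list was 0.0098, and it was 0.26 with an estimated correlation, 0.63 without a filter on low counts, 0.24 without WT replicate 1, 0.21 without FLCN KO replicate 1 and 0.086 without FLCN KO replicate 2. With fry, on the same 2 tested members, the list had an adjusted p of 0.0069. Without FLCN KO replicate 3, 1 of its members rose, and 0 rose without WT replicate 2, WT replicate 3, FLCN KO replicate 1 or FLCN KO replicate 2. Fibroblast markers summed to 83.1 ± 21.8 and 138 ± 11.7 CPM. Of 6 tested, 1 rose and 0 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.23, fry 0.039), namely SPARC, a matrix protein gene, from 4.04 ± 1.16 to 59.6 ± 12.7 CPM (adjusted p = 0.00032), while COL1A1, chosen after its values were seen, had 55.6 ± 17.4 CPM in WT and 50.3 ± 3.75 CPM in FLCN KO (adjusted p = 0.69). Fibroblast markers that rose numbered 3 without WT replicate 1.

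Of 7 tested endothelial markers, 0 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.68), with sums of 82.2 ± 14.5 and 76.3 ± 17.2 CPM. EMCN fell from 5.58 ± 0.95 to 3.12 ± 0.37 CPM (adjusted p = 0.040) and VWF from 1.47 ± 0.17 to 0.65 ± 0.16 CPM (0.040). The median of this list, −0.37, and its test were negative and its mean, 0.18, positive, and the median was 0.10 without WT replicate 1. Without WT replicate 1, 2 members rose and 2 fell, and without each of the other 5 libraries 0 were called. Adipocyte markers summed to 301 ± 17.2 and 1291 ± 329 CPM, a change carried by CD36, a fatty acid receptor gene, which rose from 289 ± 19.0 to 1285 ± 328 CPM (adjusted p = 0.00093). Of 4 tested, 1 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.68), the latter being the lipid droplet gene PLIN4, from 9.88 ± 1.496 to 2.04 ± 0.32 CPM (0.00082). The 1 testable erythroid marker, SLC4A1, had 0.27 ± 0.084 and 0.12 ± 0.062 CPM (adjusted p = 0.17, camera adjusted p of the list = 0.25), and 1 fell adjusted over the list alone. The 2 testable muscle markers, TNNC2 (adjusted p = 0.23) and ACTA1 (0.76), were not called in edgeR (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, 0 in DESeq2, 0 in limma-voom, camera adjusted p = 0.34).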

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

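Tests with WT replicates 2 and 3 against FLCN KO replicates 1 and 2, and those with the close pairs summed, were chosen after the data were seen. No paired analysis was possible because the labels of the groups share no replicate numbers. Of the 1582 genes called with all 6 libraries, 0 changed sign among those tested under each of the 16 alternatives, which were 1089 with the stricter filter and at least 1580 with the others. All 1582 had no overlap between the groups, so leaving out or summing libraries could hardly change a sign. The count of 0 is therefore no test of the calls. Of the 71 called named genes, 71 were kept with DESeq2 and without WT replicate 1, 65 with upper-quartile scaling, 45 without FLCN KO replicate 1 and 33 with the close pairs summed. Without WT replicate 1 only the close WT pair is left, and its small spread makes calls easier to keep. The MiT/TFE, lysosomal, vacuolar ATPase, autophagy and NF-kappaB lists kept their call in 11 of 11 alternatives, not counting the estimated correlation and the pair of comparisons added later, with adjusted p up to 0.0033, 0.0069, 0.013, 0.013 and 0.013. Depth limits genes such as MYO7B, RENBP and CSF1R, with at most 6 counts over the WT libraries. Fewer libraries or genes enter where replicates are left out, pairs are summed or the filter is stricter. Other causes were not tested.

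Leaving out 1 library at a time gave 579 to 4180 changed genes in place of 1582 (436 to 2234 higher, 124 to 1946 lower), and 473 to 1718 changed at least 2-fold in place of 882 (365 to 967 higher, 108 to 751 lower). The highest counts came without WT replicate 1 (4180), and the others were 591, 601, 585 and 579 without WT 2, WT 3, FLCN KO 1 and FLCN KO 2, and 1280 without FLCN KO 3. No filter gave 2409 genes (868 lower, 577 lower at least 2-fold), the stricter filter 1044 (670 higher) and 406 at least 2-fold (297 higher, 109 lower), and DESeq2 2570 (1630 higher, 940 lower). WT 2 and 3 against FLCN KO 1 and 2 gave 10298 (5337 higher, 4961 lower) and 2326 at least 2-fold (1166 and 1160), and the close pairs summed gave 217 (172 higher, 45 lower), with 217, 172 and 45 at least 2-fold. Upper-quartile scaling called 775 higher and 781 lower, and library totals 812 and 664, against 1037 and 545, with medians over all genes of −0.126, −0.079 and −0.016.

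FLCN had log2 fold changes of 0.81 to 1.06 without 1 library, with adjusted p of 0.0013 to 0.066, and 0.78 with the close pairs summed (adjusted p = 0.25). Uncalled genes changed sign. ALDOA went from 0.042 to −0.027 with library totals, −0.063 with upper quartile, −0.013 with the stricter filter, −0.097 with summed pairs and −0.037 to 0.19 without 1 library. ATP5F1B was −0.031, −0.078 and −0.026 with library totals, upper quartile and the stricter filter. COX4I1 was −0.046 with upper quartile and −0.097 to 0.21 without 1 library. MCM7 was −0.0051 with upper quartile, −0.0096 with the 2 against 2 libraries and −0.0017 to 0.18 without 1 library. MT-CO2 was 0.0056 with no filter, 0.0048 with DESeq2, 0.015 with the 2 against 2 libraries and −0.11 to 0.12 without 1 library. TFE3 was 0.089 and GAPDH 0.0040 with the 2 against 2 libraries, and without 1 library TFE3 lay at −0.16 to 0.016 and ACTA1 at −0.72 to 0.062.

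List values below are adjusted p. With an estimated correlation they were 0.262 for MiT/TFE targets, lysosomal genes, NF-kappaB targets and leukocyte markers, 0.318 for vacuolar ATPase, 0.266 for autophagy, 0.799 for hypoxia-inducible factor targets and nuclear respiratory genes, and 0.61 for cholesterol. With fry they were 0.372 for hypoxia-inducible factor targets, 0.508 for nuclear respiratory genes, 0.0782 for cholesterol, 0.0222 for interferon, 0.00691 for leukocyte markers, 0.0385 for fibroblast markers and 0.809 for adipocyte markers, the last with the direction turned. Interferon was 0.0327 with library totals, 0.0127 with the stricter filter, 0.00518 with no filter and 0.0191 to 0.143 without 1 library. No filter gave 0.00739 for angiogenic factors, 0.0672 for nuclear respiratory genes, 0.634 for leukocyte markers and 0.973 for basal genes (turned). The stricter filter turned mitochondrially encoded genes (0.79), mitochondrial biogenesis (0.912), cell cycle (0.874) and adipocyte markers (0.874). WT 2 and 3 against FLCN KO 1 and 2 gave 1.66e-05 for glycolysis, 0.0269 for angiogenic factors, 0.353 for cell cycle (turned), 0.0979 for cholesterol and 0.178 for leukocyte markers. Summed pairs gave 0.0884 for hypoxia-inducible factor targets, 0.179 for nuclear respiratory genes, 0.961 for mitochondrially encoded genes (turned) and 0.132 for leukocyte markers.

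Without 1 library, glycolysis lay at 0.000922 to 0.565, angiogenic factors at 0.00652 to 0.351, cholesterol at 0.00229 to 0.143, leukocyte markers at 0.00523 to 0.237, hypoxia-inducible factor targets at 4.63e-11 to 0.129, nuclear respiratory genes at 8.59e-05 to 0.452 and estrogen receptor targets at 0.0385 to 0.513. Calls began for glycolysis and angiogenic factors without WT 1, for interferon without WT 2 (0.0215) and FLCN KO 3 (0.0191) and for estrogen receptor targets without FLCN KO 3. They ended for cholesterol without WT 1, for hypoxia-inducible factor targets without WT 2 (0.118) or WT 3 (0.129), for nuclear respiratory genes without WT 2 (0.173), WT 3 (0.438) or FLCN KO 3 (0.452) and for leukocyte markers without WT 1 (0.237), FLCN KO 1 (0.214) or FLCN KO 2 (0.0857). Never called, but turned in direction without some library, were cell cycle (0.379 to 0.728), mitochondrially encoded genes (0.529 to 0.991), basal genes (0.595 to 0.974) and ATF4 targets (0.111 to 0.981).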

Other observations

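The tests of leukocyte gain, of host cells and KO RNA in WT replicate 1 and of a hypoxic state were chosen after the result was seen, as were the gene groups of the next 2 paragraphs.

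Some genes of antigen presentation rose in the KO-labelled libraries and others were not called. NLRC5, the transactivator of class I genes, rose from 0.87 ± 0.17 to 11.9 ± 2.41 CPM (log2 fold change 3.76 ± 0.24, edgeR adjusted p = 0.00023) and B2M, the class I light chain gene, from 365 ± 25.4 to 788 ± 116 CPM (1.11 ± 0.14, 0.0030). Of 17 tested genes and pseudogenes with an HLA symbol, 8 rose and 0 fell, among them HLA-A (0.94), HLA-B (1.14), HLA-C (0.59) and the class II genes HLA-DRA (2.63) and HLA-DPA1 (2.71), although reads shared between these paralogs make each value uncertain. TAP1 (adjusted p = 0.51), TAP2 (0.21), PSMB9 (0.14) and 9 of the HLA-symbol genes, among them HLA-DRB1 (0.21), HLA-F (0.16) and HLA-DMA (−0.25 on the log2 scale, 0.40), were not called. The leukocyte markers CSF1R (3.71) and ITGAM (2.06) rose in the same libraries, and whether leukocytes account for these genes was not tested and stays open.

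Of 3 genes for hypoxia-inducible factor subunits, 2 rose. HIF1A went from 117 ± 26.9 to 369 ± 105 CPM (1.66 ± 0.24, edgeR adjusted p = 0.0054) and EPAS1 from 10.3 ± 0.40 to 24.9 ± 1.38 CPM (1.27 ± 0.12, 0.0012), while ARNT was not called (adjusted p = 0.50). Of the 4 Rag GTPase genes, RRAGD rose from 9.80 ± 7.22 to 104 ± 18.0 CPM (3.40, adjusted p = 0.0051) and RRAGC from 12.8 ± 1.64 to 29.8 ± 3.89 CPM (1.22, 0.0039), and RRAGA and RRAGB were not called. RRAGC and RRAGD belong to the MiT/TFE list above, so their rise is no separate result. Among 5 perilipin genes of the lipid droplet, PLIN2 rose (1.51, adjusted p = 0.015) and PLIN4 (−2.27, 0.00082) and PLIN5 (−2.03, 0.0012) fell. Of 9 laminin genes, LAMA4, LAMC2, LAMB3 and LAMB1 rose and 0 fell.

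The first pattern is the set of changed genes itself. The real grouping called 1582 genes, and the other 9 splits of the 6 libraries 3 against 3 called at most 0 in edgeR (no other tool was run on them, and 2918 genes at most had an unadjusted p under 0.05, against 4644), so 1 of 10 splits, the real one, reached that count. Each of the other splits holds WT and FLCN KO libraries on both sides. A group difference then widens the spread within each side, which by itself lowers the number of calls in edgeR. Part of the group difference also remains between the sides, so a list that differs can be called in such splits. For genes changed at least 2-fold the values were 882 and at most 0, again 1 of 10 splits. For lists in camera with the preset correlation the real grouping called 9 and another split 10, and 3 of 10 splits reached 9, and with 10 splits no share under 0.05 can be had for any of the 3 counts. Copy-number differences over large segments were argued against as the main source, since windows of 50 neighbouring genes with a median log2 fold change over 0.25 in size held 9.01% of the changed genes. They held 5.99% of all genes, however, and there were 21 such windows of 349 and at most 4 in 1000 shuffles of gene order.

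The second pattern is that WT replicate 1 stood apart from WT replicates 2 and 3, for which RNA of a KO tumor was argued against, since 9 genes near-silent in WT replicates 2 and 3 and expressed in the KO-labelled libraries implied a median KO share of 0.37%. For more host cells, 39 markers of fibroblasts, endothelial cells, leukocytes and adipocytes under 1 CPM in WT replicates 2 and 3 were summed. Their sum was 3.92 CPM on average in WT replicates 2 and 3 and 7.72 CPM in WT replicate 1. This gain was 0.0047% of what all genes higher in WT replicate 1 gained (3.80 against 81532 CPM). That percent cannot decide, because the markers were taken for their low level and mouse reads enter only where they align to human genes. More host cells therefore stay open. The planned sums over all members (fibroblast 1.53-fold, leukocyte 1.32-fold, adipocyte 0.91-fold and endothelial 0.73-fold) decided nothing, because COL1A1, CD36 and EGFL7 held 64.6%, 96.5% and 84.9% of the fibroblast, adipocyte and endothelial sums. Length or GC content lowered the SD of the deviation by 4.08%, with Spearman rho across genes of 0.29 and −0.14, and removing medians of segments lowered it by 1.34%, so neither trend accounts for most of it, although 29 of 349 windows of neighbouring genes had a median deviation over 0.25 in size and shuffles gave at most 11. A hypoxic state of that tumor stays open and was not tested independently of the values that raised it, a median deviation of 1.48 for the 27 hypoxia-inducible factor targets against 0.20 at the 95th percentile of 10000 expression-matched random lists, and handling was not tested either.

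The third pattern is the rise of lysosomal and MiT/TFE target genes. What had been written beforehand for more leukocytes as the cause was met, since the 14 leukocyte markers summed to 1.34 to 2.38 CPM in the KO-labelled libraries and 0.74 to 1.06 CPM in WT (means 1.89 and 0.89), a rise at least as large as the lysosomal median of 0.78 on the log2 scale. On amount, a criterion chosen afterwards, the markers gained 0.013% of what the 57 lysosomal and MiT/TFE target genes gained (1.00 against 7791 CPM). CSF1R and ITGAM carried that gain, and the other markers together went from 0.62 to 0.43 CPM. Few leukocyte marker reads were thus counted. Reads of mouse host leukocytes enter only where they align to human genes, by a share not measured for markers or for lysosomal genes. The amount therefore cannot decide, and leukocytes stay open. Scaling was argued against, with a median of 0.66 for the lysosomal list under the least favourable scaling. The genotype given by the labels, or another difference between the 2 cell stocks, stays open as an untested explanation.

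FLCN KO replicate 3 differed from FLCN KO replicates 1 and 2 in 42 of 349 windows of neighbouring genes, where shuffles gave at most 4. Its hypoxia-inducible factor targets lay at a median of 0.090 from FLCN KO replicates 1 and 2, the 72.1st percentile of random lists. Across genes, its deviation and that of WT replicate 1 correlated at r = 0.38, and genes are not independent replicates.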
